A study of Arabidopsis thaliana with 22 samples.

How the data were processed

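Gene expression was measured on 22 one-colour arrays of Arabidopsis thaliana root cells, with 2 or 3 arrays in each of 8 groups. The groups combine 2 genotypes (Col0 and the mutant atscl26), 2 sorted cell types (epidermis and cortex) and 2 treatments (KNO3 and control). Per the labels' protocols, seedlings grew for 9 days on plates with 0.1 mM KNO3 and 30 mM sucrose, were treated for 2 h, and their roots were then turned into protoplasts. Cells carrying a GFP reporter of epidermis or cortex were sorted by fluorescence, and their RNA was amplified, labelled with Cy3 and hybridised to NimbleGen arrays designed on TAIR10. The source names give an age of 12 days where the protocol gives 9 days, and the sample titles name KCl (5 mM in the source names) as the control where the protocol describes plates kept at 0.1 mM KNO3. The 2 versions cannot be settled from the sources used here, and the control is called KCl below, as in the titles.

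The deposited values are log2 expression values made by RMA, per the submitters' processing notes, with 1 value per transcript model and array. RMA settings and software version are not given in the sources used here. Per the series description, 24 arrays were made and the submitters removed 2 after normalisation for low quality scores (replicate 3 of atscl26 epidermis KCl and replicate 3 of Col0 cortex KNO3). The value table holds 31524 transcript models of 27143 loci, of which 3675 have more than 1 model. The number at the end of each ID was read as that of the transcript model, which the sources used here do not state. A second deposited table holds the authors' log2 averages per group, and it was compared with the group means but entered no test. Names came from a table of TAIR10.1 genes, used for names only. It held the locus of 30935 models (26555 loci) and gave a symbol other than the locus for 12507 models. SCL26 is named from the labels, as locus AT4G08250.

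The log2 values were used as deposited. A linear model with 1 mean per group was fitted to all 22 arrays with limma 3.58.1 (R 4.3.3), which left 14 residual degrees of freedom, and contrasts were tested with the moderated statistics of eBayes (17.7 total degrees of freedom). The p-values were adjusted by the Benjamini-Hochberg method over all 31524 models within each comparison, and the threshold was an adjusted p under 0.05. The limma p-values of single models measure the spread between arrays that the labels call biological replicates. There were 15 comparisons. They were the nitrate effect (KNO3 minus KCl) in each genotype and cell type, the genotype effect (atscl26 minus Col0) in each cell type and treatment, the genotype by nitrate interaction in each cell type, the cell type effect (epidermis minus cortex) in Col0 KCl, its interaction with nitrate in Col0, and the average effect of each factor over the other 2. The number of arrays limits the precision. The median standard error of a log2 difference lay between 0.688 and 1.03, except in the average effects, where it was 0.365.

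Before the data were examined, 22 gene lists were fixed: nitrate uptake and reduction, reductant supply, nitrate response regulators, ammonium assimilation, nitrogen starvation transporters, gibberellin biosynthesis, gibberellin catabolism, gibberellin signalling, GASA gibberellin-regulated peptides, the GRAS family outside the DELLA proteins, auxin and lateral root, cytokinin synthesis and response, wound, heat and protoplasting stress, iron deficiency, phosphate starvation, cell cycle, and markers of non-hair epidermis, root hairs, cortex, endodermis, stele and root cap. Of 253 members, 4 were left out because the reference assigned their symbol to another locus (SCL28, SCL30, SCL33 and PEP). SCR, SHR and SCL3 each stand in 2 lists. Lists were tested with camera in limma, with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists of a comparison, 330 tests in all. A camera p-value compares list members with the other models. With the preset it rests on the spread over models and an assumed correlation, not on the spread between replicates alone. The same tests were run with the correlation estimated from the data. Named genes follow a rule fixed in advance: SCL26 in every comparison, every model past the threshold, and, where none passed, the 3 higher and 3 lower models with the smallest p, of which those without a symbol could be left out of the text. For each list the members past the threshold, or up to 2 with the smallest p, could be named. Members were also adjusted over their list alone in each of the 330 tests. That adjustment does not cover the other lists or comparisons, so some members pass it by chance. The values of 1 list member are not reported here. NIA1, NIA2, NIR1, NRT1.1 and NRT2.1 were named as nitrate-responsive genes after their values were seen.

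Each array's median correlation with the other arrays was computed over all models. A marker score per array was the mean of 16 epidermis markers minus the mean of 3 cortex markers, and an array was called discordant where its score lay nearer to the median of the other cell type. The alternatives were quantile normalization of the deposited values, leaving out the 30% of models with the lowest mean, the replicate number as a fixed block, only the compared groups in the fit, 1 model per locus, array weights, an intensity trend with a robust prior, and leaving out each array in turn. Leaving out 4 arrays with low correlation, leaving out the discordant arrays, and leaving out each array in turn for the list tests were added after the data had been seen. Leaving out the discordant arrays was not run for the cell type comparisons, since the score that picks those arrays measures cell type. In the other comparisons it leaves some groups with 1 array, and the epidermis and cortex marker lists hold the genes of the score, so their change under it is no test. The counts of transcript models and lists were also recomputed on other splits of the arrays, all 10 for 3 arrays against 3 and 100 drawn with seed 1 for the average effects.

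The code was tested on simulated data in which 200 of 31524 models were changed. With the unequal array spreads seen in the data, the simulated nitrate effect in Col0 epidermis was recovered for 2% of models at a log2 change of 1, 20% at 2, 70% at 4 and 94% at 6, with 50 models per size. In that simulation 86 of the 179 calls fell on unchanged models. With equal array spreads, 4 of 106 calls did. For the average cell type effect, recovery was 10%, 66%, 96% and 100% at the same sizes, with 15 of 151 calls on unchanged models, or 4 of 145 with equal spreads.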

Results

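Root cells of Arabidopsis thaliana were compared between 2 genotypes, 2 sorted cell types and 2 treatments. Each group has n = 3 arrays, except atscl26 epidermis KCl and Col0 cortex KNO3, which have n = 2. SCL26, the gene mutated in atscl26, encodes a GRAS transcription factor, and the series asks how it links gibberellin and nitrogen in the control of root architecture. Array medians lay between 8.78 and 9.04 on the log2 scale and the lowest value was 5.05. Differences below are log2 differences ± SE from limma unless stated otherwise, with p adjusted by Benjamini-Hochberg.

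SCL26 (AT4G08250) did not separate the genotype labels. Its median was 7.94 in the 11 arrays labelled Col0 (range 7.0 to 11.26) and 8.30 in the 11 labelled atscl26 (range 7.66 to 9.11). By group, the mean SCL26 level ± SD was 9.07 ± 1.95 in Col0 epidermis KCl, 8.11 ± 0.64 in Col0 epidermis KNO3, 7.79 ± 0.30 in Col0 cortex KCl and 8.74 ± 2.46 in Col0 cortex KNO3. In arrays labelled atscl26 it was 7.74 ± 0.11 in epidermis KCl, 8.71 ± 0.40 in epidermis KNO3, 8.33 ± 0.39 in cortex KCl and 8.52 ± 0.76 in cortex KNO3. The highest levels, 11.26 and 10.48, came from replicate 2 of Col0 epidermis KCl and replicate 1 of Col0 cortex KNO3, which correlated poorly with all other arrays. In every other array labelled Col0, SCL26 lay between 7.0 and 8.82 and below the median of that array. Such low levels leave little room for a loss to show. The type of mutation and the position of the probes in the gene are not given in the sources used here, so a mutant transcript without function could still be measured. Genotypes are therefore given as labelled throughout.

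**Figure D1:**
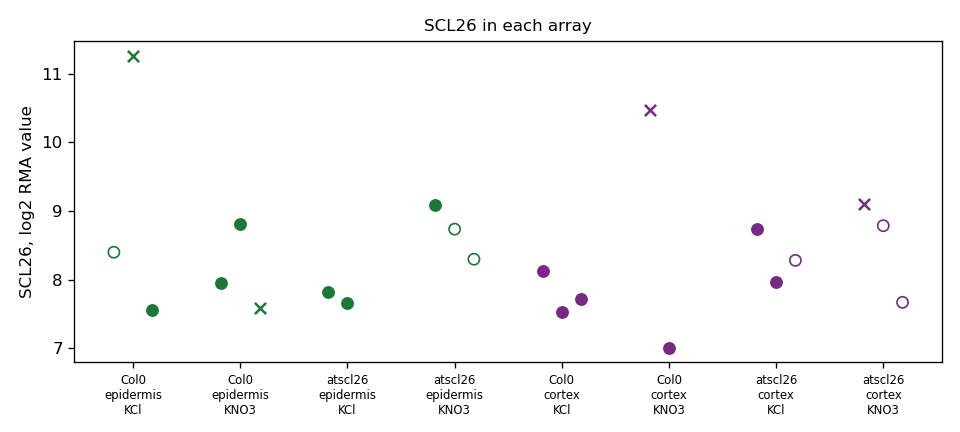
Log2 RMA value of SCL26 in each of the 22 arrays by labelled group, replicates 1 to 3 from left to right, with epidermis in green, cortex in purple, open circles for arrays whose marker score lies nearer the other cell type and crosses for the 4 low-correlation arrays. Levels in arrays labelled atscl26 (7.66 to 9.11) lie within the range of those labelled Col0 (7.0 to 11.26).

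The marker score lay on the side of the cell type label in 15 arrays and nearer the other cell type in 7. WER, a MYB factor of non-hair epidermal cells, spanned 7.73 to 13.51 in all arrays labelled epidermis and 7.24 to 13.24 in all labelled cortex. Among well correlated arrays with a score on the side of the label, WER lay between 11.92 and 13.51 in 6 labelled epidermis and between 7.24 and 10.52 in 6 labelled cortex. RHD6, which starts root hair formation, lay between 11.51 and 13.05 in the former and 7.82 and 9.58 in the latter. The inhibitor gene C/VIF2, used here as a cortex marker, went the other way, with 8.05 to 8.97 and 10.39 to 11.80. WER, RHD6 and C/VIF2 are part of the score that picked these arrays, so their separation there is no test of the labels. In 6 further arrays the marker score, the mean of the epidermis markers minus that of the cortex markers, lay nearer the other cell type, though not every single marker did. Among these, WER was 8.62 to 11.22 in 3 arrays labelled epidermis (replicate 1 of Col0 KCl, replicates 2 and 3 of atscl26 KNO3) and 12.95 to 13.24 in 3 labelled cortex (replicate 3 of atscl26 KCl, replicates 2 and 3 of atscl26 KNO3). C/VIF2 was 10.49 to 11.89 and 8.31 to 9.71 in the same arrays. WER of 11.22 (replicate 1 of Col0 epidermis KCl) and 10.54 (replicate 2 of atscl26 epidermis KNO3) lay between the levels of the first 2 sets, and the cortex marker AT1G62510, at 11.31 in replicate 2 of atscl26 cortex KNO3, did not leave the side of its label. The 4 remaining arrays had low correlations, with medians of 0.562 (Col0 epidermis KCl, replicate 2), 0.681 (Col0 cortex KNO3, replicate 1), 0.772 (atscl26 cortex KNO3, replicate 1) and 0.800 (Col0 epidermis KNO3, replicate 3), against 0.852 to 0.921 in the other 18. Of these 4, replicate 2 of Col0 epidermis KCl was discordant as well, with a marker score of -1.90.

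**Figure D2:**
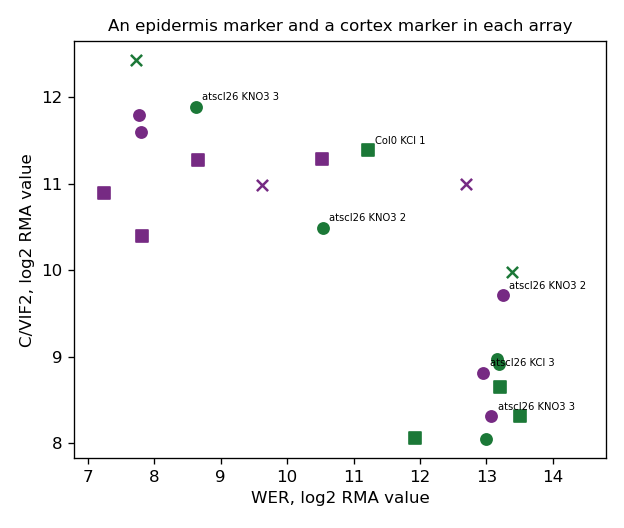
Log2 RMA values of the epidermis marker WER and the cortex marker C/VIF2 in each array, labelled epidermis in green and cortex in purple, with squares for Col0, circles for atscl26 and crosses for the 4 low-correlation arrays. The 6 well correlated arrays whose marker score lies nearer the other cell type had WER at 8.62 to 11.22 where labelled epidermis and at 12.95 to 13.24 where labelled cortex. Of the former, 2 values lay between those of the cell types in the other well correlated arrays.

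**Figure D3:**
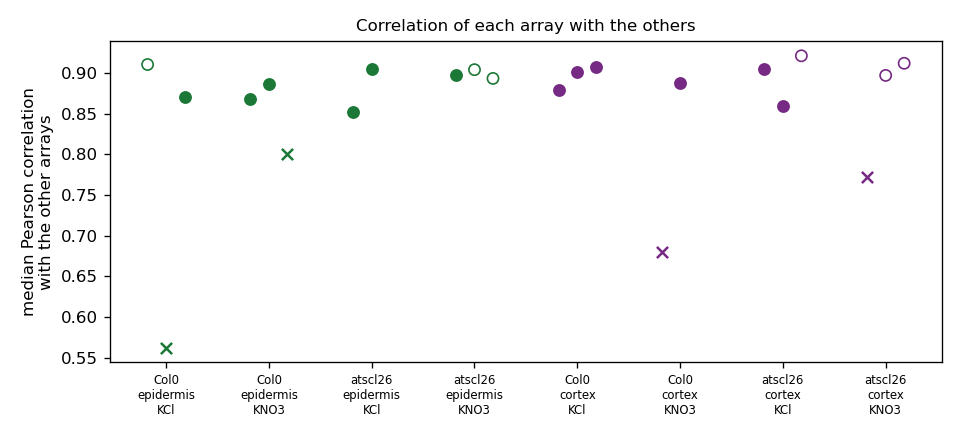
Median Pearson correlation of each array with the other 21 over all transcript models, by labelled group, with colours and symbols for cell type, marker side and low correlation as in the plot of SCL26. The 4 crosses lie between 0.562 and 0.800 and the other 18 arrays between 0.852 and 0.921.

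The nitrate effect in Col0 epidermis compares KNO3 with KCl (n = 3 and 3). No transcript model passed the threshold in limma, and 1711 had an unadjusted p under 0.05, 1011 higher and 700 lower. With uniform p-values 1576 would be due by chance. The 10 splits of these arrays had a median of 2085, and all 10 gave at least 1711, so this is no excess. The smallest p among symbols belonged to emb2738, needed for embryo development, at 3.44 ± 0.59, and to PAL4, a phenylalanine ammonia-lyase of phenylpropanoid synthesis, at -2.31 ± 0.43 (adjusted p = 0.491 for both), and SHL1 differed by -2.55 ± 0.54 (adjusted p = 0.517). PAL4 passed with quantile normalization (adjusted p = 0.0197), with array weights (0.0082) and without the 4 low-correlation arrays (0.0301). It did not pass with the replicate block or with an intensity trend and robust prior. SCL26 differed by -0.96 ± 0.83. The genes of nitrate assimilation did not pass: NIA1, a nitrate reductase, differed by -0.68 ± 0.53, NIR1, the nitrite reductase, by 0.68 ± 0.77, and NRT2.1, a high-affinity nitrate transporter, by -0.81 ± 0.94 (adjusted p = 0.977, 0.979 and 0.979). The list of reductant supply, which feeds electrons to nitrite reduction, rose as a group in camera (7 of 8 members higher, median 0.52, adjusted p = 0.0303; adjusted p = 0.696 with an estimated correlation). Its examples were G6PD3, of the pentose phosphate pathway, at 2.26 ± 0.86 and RFNR1, a root ferredoxin reductase, at 2.28 ± 1.04. Cell cycle genes rose (10 of 11 higher, median 0.84, adjusted p = 0.0269; adjusted p = 0.696 with an estimated correlation), with the mitotic kinase CDKB2;2 at 2.07 ± 0.87 and the cyclin CYCB1;1 at 1.18 ± 0.74. Endodermis markers fell (0 of 11 higher, median -1.44, adjusted p = 0.0096; adjusted p = 0.696 with an estimated correlation), with the Casparian strip proteins CASP2 at -1.69 ± 0.93 and CASP5 at -1.05 ± 0.65. Beside these groups, the mean level of the endodermis markers was 11.50, 9.16 and 7.10 in the 3 KCl arrays and 7.26, 8.71 and 7.94 in the 3 KNO3 arrays. Without the discordant arrays, which leaves 1 KCl array, the medians were -0.48 for cell cycle and 0.86 for endodermis markers. Reductant supply lost its call with quantile normalization (median 0.34, camera adjusted p = 0.0764), with dim models left out (0.101, median 0.515) and without the 4 low-correlation arrays (0.144, median 0.468). Cell cycle lost it with dim models left out (0.077, median 0.843) and array weights (median 0.338, adjusted p = 0.623), and endodermis markers with array weights (median 0.234, adjusted p = 0.896).

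The nitrate effect in Col0 cortex (n = 2 KNO3, n = 3 KCl) gave no model past the threshold in limma and 1601 with an unadjusted p under 0.05, 595 higher and 1006 lower. ABCE1, of the family of ribosome recycling factors, differed by 4.91 ± 0.83 (adjusted p = 0.425) and emb2726 by 3.15 ± 0.63 (adjusted p = 0.767), and SCL26 by 0.95 ± 0.93. NIR1 differed by -2.08 ± 0.87, NIA1 by -0.31 ± 0.59 and NRT2.1 by 0.97 ± 1.05 (adjusted p = 0.896, 0.912 and 0.896). Reductant supply fell as a group in camera (7 of 8 members lower, median -1.05, adjusted p = 0.00132; adjusted p = 0.757 with an estimated correlation). RFNR2, a ferredoxin reductase, differed by -2.79 ± 0.94 and PGD3, of the pentose phosphate pathway, by -1.03 ± 0.48. Of the 2 KNO3 arrays, replicate 1 had a median correlation of 0.681 and an endodermis marker mean of 10.61, against 0.888 and 7.75 in replicate 2. Without the 4 low-correlation arrays, which leaves replicate 2 alone and assumes that it varies like the other groups, 24 models passed and the reductant supply call was lost (median -0.47, adjusted p = 0.426 in camera).

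Whether nitrate acted differently in the cell types of Col0 was tested as the cell type by nitrate interaction (n = 2 and 3 in cortex, 3 and 3 in epidermis). No model passed in limma and 2051 had an unadjusted p under 0.05. AGL26 differed by 3.39 ± 0.78, SCO3 by 4.43 ± 1.03 and ABCE1 by -5.68 ± 1.12 (adjusted p = 0.761 for each), and SCL26 by -1.91 ± 1.25. The nitrate effect on reductant supply was more positive in epidermis (8 of 8 members, median 1.60, camera adjusted p = 0.000238; adjusted p = 0.691 with an estimated correlation). G6PD3 (4.02 ± 1.29), PGD3 (1.96 ± 0.64), RFNR1 (4.08 ± 1.55) and RFNR2 (3.45 ± 1.27) were the 4 members that passed when adjusted over the list alone, and none of these passed over all models. Cell cycle genes differed the same way (9 of 11 higher, median 1.00, adjusted p = 0.0319; adjusted p = 0.691 with an estimated correlation), among them the replication factor MCM2 at 3.32 ± 1.43 and the cytokinesis syntaxin KNOLLE at 3.3 ± 1.63. Endodermis markers (10 of 11 lower, median -2.10, adjusted p = 0.00554) and stele markers (12 of 14 lower, median -1.24, adjusted p = 0.0142) differed the other way, both with adjusted p = 0.691 with an estimated correlation. The phloem sucrose transporter SUC2 differed by -1.91 ± 0.85 and the phosphate exporter PHO1 by -1.83 ± 0.86. The arrays with endodermis marker means of 11.50 (Col0 epidermis KCl, replicate 1) and 10.61 (Col0 cortex KNO3, replicate 1) both enter this interaction with the sign of the observed shift. Without the 4 low-correlation arrays, which leaves 1 array in cortex KNO3, the reductant, endodermis and stele calls were lost (camera adjusted p = 0.0789, 0.262 and 0.818, medians 0.796, -1.01 and -0.0311). With dim models left out the cell cycle and stele calls were lost (0.195 and 0.231, medians 1.00 and -0.728). Array weights ended those of cell cycle, endodermis and stele (0.527, 0.608 and 0.527, medians 1.15, -0.801 and -0.478).

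The nitrate effect in epidermis labelled atscl26 (n = 3 KNO3, n = 2 KCl) gave no model past the threshold in limma and 1021 with an unadjusted p under 0.05, 520 higher and 501 lower. The transcription factor TCP8 differed by 2.74 ± 0.60 and SULA by -2.49 ± 0.55 (adjusted p = 1 for both), SCL26 by 0.97 ± 0.93, NIA1 by -0.25 ± 0.59, NIR1 by 0.33 ± 0.87 and NRT2.1 by -1.08 ± 1.05. In camera 3 marker lists moved. Non-hair markers fell (0 of 6 higher, median -1.30, adjusted p = 0.00465), with the homeodomain factor GL2 at -1.71 ± 0.88 and TRY at -1.73 ± 0.92. Cortex markers rose (3 of 3 higher, median 1.97, adjusted p = 0.034), with AT1G62510 at 2.58 ± 1.11 and C/VIF2 at 1.97 ± 1.13, and endodermis markers rose (11 of 11 higher, median 1.47, adjusted p = 0.00256), with MYB36, a regulator of endodermal differentiation, at 3.08 ± 1.76 and the receptor kinase SGN3 at 2.05 ± 1.32. All 3 calls had an adjusted p = 0.59 with an estimated correlation. SPX1, a phosphate sensor, passed when adjusted over the list alone (2.91 ± 0.98, adjusted p = 0.0498) and not over all models. Of the KNO3 arrays, replicates 2 and 3 had marker scores of -1.29 and -3.53 against 0.99 in replicate 1, and without the discordant arrays, which leaves 1 KNO3 array, the endodermis median was -0.12 (camera adjusted p = 0.98). The non-hair and cortex markers are part of the score that picks these arrays, so their change is no test. The cortex call was also lost with quantile normalization (camera adjusted p = 0.0703), dim models left out (0.067), array weights (0.0565) and without the 4 low-correlation arrays (0.0851), with medians of 1.81 to 2.32.

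The nitrate effect in cortex labelled atscl26 (n = 3 and 3) gave no model past the threshold in limma and 859 with an unadjusted p under 0.05, 372 higher and 487 lower. ATMYC1, a bHLH factor of epidermal fate, differed by 3.71 ± 0.78, the Rab GTPase RABA5b by 3.33 ± 0.71, the poly(ADP-ribose) polymerase PARP2 by 2.33 ± 0.51 and AAE3, an oxalyl-CoA synthetase, by -2.98 ± 0.59 (adjusted p = 1 for each). SCL26 differed by 0.19 ± 0.83, NIA1 by -0.12 ± 0.53, NIR1 by -0.47 ± 0.77 and NRT2.1 by 0.56 ± 0.94. The GRAS family outside the DELLA proteins fell in camera (18 of 22 members lower, median -0.70, adjusted p = 0.000925; adjusted p = 0.247 with an estimated correlation), with SCL11 at -1.22 ± 0.54 and PAT1, of phytochrome signalling, at -2.74 ± 1.35. Reductant supply fell (7 of 8 lower, median -0.53, adjusted p = 0.0127), with RFNR2 at -1.76 ± 0.84 and the ferredoxin FD3 at -0.82 ± 0.43. Non-hair markers rose (5 of 6 higher, median 0.76, adjusted p = 0.0127) with WER at 3.49 ± 1.45 and EGL3 at 2.11 ± 1.01, and root hair markers rose (9 of 10 higher, median 0.75, adjusted p = 0.0342) with RHD6 at 2.21 ± 1.17, while the NADPH oxidase RHD2 was at -1.79 ± 0.80. These 3 calls had an adjusted p = 0.58 with an estimated correlation. The ammonium transporter AMT2 passed when adjusted over the list alone (-3.44 ± 1.07, adjusted p = 0.0482) and not over all models. Replicates 2 and 3 of KNO3 and replicate 3 of KCl were the discordant arrays, with non-hair marker means of 11.23, 10.96 and 11.17, against 10.47 in the other KNO3 array and 8.55 and 9.20 in the other KCl arrays. Without them 89 models passed, with 1 low-correlation KNO3 array left, and all 4 list calls were lost (camera adjusted p = 0.285 to 0.539). The medians in the order above were then -0.55, -1.03, 0.90 and 0.95, which decides nothing about the source of the shifts, since 1 array is the whole KNO3 group and the hair and non-hair markers are part of the score. With dim models left out the reductant and root hair calls were lost (0.0892 and 0.153, medians -0.529 and 0.718).

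The genotype by nitrate interaction in epidermis asks whether nitrate acted differently under the atscl26 label (n = 2 to 3 per group). No model passed in limma and 1934 had an unadjusted p under 0.05. SRC2, a C2-domain protein, differed by 5.55 ± 0.98 and the mitotic Aurora kinase AUR1 by -4.57 ± 0.86 (adjusted p = 0.28 for both), and SCL26 by 1.93 ± 1.25. Endodermis markers were more positive under nitrate in atscl26 (11 of 11, median 3.02, camera adjusted p = 4.87e-05), with SGN3 at 3.77 ± 1.77 and CASP5 at 1.75 ± 0.97, as were cortex markers (3 of 3, median 3.79, adjusted p = 0.00764) and the GRAS family (16 of 22, median 0.56, adjusted p = 0.0418), with SCL11 at 2.36 ± 0.81 and SCL3, which acts against DELLA proteins, at 2.99 ± 1.37. All 3 calls had an adjusted p = 0.522 with an estimated correlation. The cortex markers AT1G62510 (4.76 ± 1.49) and C/VIF2 (3.79 ± 1.52) passed when adjusted over the list alone (adjusted p = 0.0155 and 0.0342), not over all models. Cell cycle genes were more negative (10 of 11, median -1.03, adjusted p = 0.0264; adjusted p = 0.533 with an estimated correlation), with CYCB2;1 at -3.02 ± 1.38 and MCM2 at -2.89 ± 1.43. Endodermis marker means were 7.20, 8.58 and 10.41 in the KNO3 arrays labelled atscl26, and 11.50, 9.16 and 7.10 in the KCl arrays labelled Col0. The endodermis, GRAS and cell cycle medians were -0.98, -0.16 and 0.58 without the discordant arrays, which leaves 1 array in each of these groups. The cortex markers, part of the score that picks these arrays, cannot be judged. Array weights ended the calls of endodermis, cortex, GRAS and cell cycle (camera adjusted p = 0.174, 0.174, 0.356 and 0.331, medians 1.07, 2.46, 0.403 and -0.932). Leaving out dim models ended those of GRAS and cell cycle (0.0504 for both, medians 0.625 and -1.03). Leaving out the 4 low-correlation arrays ended those of cortex (0.0545, median 3.47) and GRAS (0.252, median 0.235).

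In cortex the same interaction (n = 2 to 3 per group) gave no model past the threshold in limma, 785 with an unadjusted p under 0.05 and no list called. GCD1 differed by 2.69 ± 0.64, ABCE1 by -4.85 ± 1.12 and AAE3 by -3.81 ± 0.89 (adjusted p = 1 for each), and SCL26 by -0.76 ± 1.25. NIR1 differed by 1.61 ± 1.16. Gibberellin biosynthesis genes were lower in 10 of 14 cases (median -0.47, camera adjusted p = 0.219) and nitrogen starvation transporters in 9 of 10 (median -0.83, adjusted p = 0.208). Without the 4 low-correlation arrays 10 models passed, and without the discordant arrays 3, but these leave 1 array in KNO3 cortex of Col0 and of atscl26, respectively, whose spread is assumed to be that of the other groups.

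The genotype effect in epidermis under KCl (n = 2 atscl26, n = 3 Col0) gave no model past the threshold in limma and 1423 with an unadjusted p under 0.05. PAL4 differed by -2.64 ± 0.48 (adjusted p = 0.529), the beta-galactosidase BGAL14 by -2.33 ± 0.48 (adjusted p = 0.848) and SCL26 by -1.33 ± 0.93 (adjusted p = 0.848). PAL4 passed with quantile normalization (adjusted p = 0.0255), array weights (0.012) and without the 4 low-correlation arrays (0.0367). It did not pass with the replicate block or with an intensity trend and robust prior. Mean PAL4 levels ± SD were 9.13 ± 0.30 in Col0 epidermis KCl and 6.49 ± 0.27 in atscl26 epidermis KCl. In camera, endodermis markers were lower in atscl26 (11 of 11, median -1.51, adjusted p = 0.000252), with the dirigent-like protein ESB1 at -2.98 ± 1.4 and the lignin peroxidase PER64 at -2.58 ± 1.37, as were cortex markers (3 of 3, median -2.23, adjusted p = 0.0494) and stele markers (13 of 14, median -0.78, adjusted p = 0.0315), with SUC2 at -1.72 ± 0.63. All 3 calls had an adjusted p = 0.669 with an estimated correlation. Cortex marker means were 10.68, 11.71 and 8.49 in the Col0 arrays, the first 2 of which were discordant, and 8.76 and 7.85 in the atscl26 arrays. Without the discordant arrays, which leaves 1 Col0 array, the endodermis and stele medians were 0.21 and 0.12, and both calls were lost. The cortex call was also lost with quantile normalization (camera adjusted p = 0.0708, median -2.36), the replicate block (0.0556, median -2.48), array weights (0.822, median -0.24) and without the 4 low-correlation arrays (0.361, median -1.37). The endodermis call was lost with array weights (0.822, median -0.216). The stele call was lost with array weights (0.968, median 0.084), with dim models left out (0.278, median -0.558) and without the 4 low-correlation arrays (0.361, median -0.195).

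In cortex under KCl (n = 3 and 3) the genotype effect gave no model past the threshold in limma, 409 with an unadjusted p under 0.05 and no list called. MLP329, of the major latex protein family, differed by -3.17 ± 0.87 (adjusted p = 1) and SCL26 by 0.54 ± 0.83. Gibberellin biosynthesis genes were lower in 8 of 14 cases (median -0.42, camera adjusted p = 0.549) and gibberellin signalling genes in 8 of 12 (median -0.26, adjusted p = 0.142).

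The genotype effect in epidermis under KNO3 (n = 3 and 3) gave no model past the threshold in limma. MAN2 (AT2G20680), a mannanase of cell wall polysaccharide breakdown, differed by 4.79 ± 0.70 (adjusted p = 0.0664 in limma), with mean levels ± SD of 11.15 ± 1.00 in atscl26 epidermis KNO3 and 6.36 ± 0.32 in Col0 epidermis KNO3. The ferritin FER1, which stores iron, differed by 2.91 ± 0.57 (adjusted p = 0.45), emb2738 by -3.51 ± 0.59 (adjusted p = 0.214), the telomere-binding protein TRB1 by -2.48 ± 0.47 (adjusted p = 0.45) and SCL26 by 0.60 ± 0.83. An unadjusted p under 0.05 was found for 1633 models, 1004 higher and 629 lower. Genes of wound, heat and protoplasting stress were higher in atscl26 (12 of 14, median 0.62, camera adjusted p = 0.0153; adjusted p = 0.777 with an estimated correlation), with the NADPH oxidase RBOHD at 2.11 ± 0.90 and the defence factor WRKY33 at 1.12 ± 0.60. This call was lost with dim models left out (median 0.621, adjusted p = 0.063). The mean cortex marker level ranged from 8.35 to 11.47 in the atscl26 arrays and from 7.90 to 9.74 in the Col0 arrays. Adjusted over the list alone, SLY1, the F-box protein that removes DELLA proteins (3.13 ± 0.84, adjusted p = 0.0196), PHO2 (-2.51 ± 0.70, adjusted p = 0.0135) and the root cap gene FEZ (-2.11 ± 0.73, adjusted p = 0.0399) passed, and none did over all models. MAN2 passed with dim models left out (adjusted p = 0.0427), with array weights (0.00116) and without the 4 low-correlation arrays (0.0204, 14 models in all). MAN2 did not pass with quantile normalization (0.314), the replicate block (0.2), only the compared groups in the fit (0.538), an intensity trend and robust prior (0.0895) or 1 model per locus (0.0547), nor without the discordant arrays (3.67, adjusted p = 1), which leaves 1 atscl26 array.

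The genotype effect in cortex under KNO3 (n = 3 atscl26, n = 2 Col0) gave no model past the threshold in limma and 1938 with an unadjusted p under 0.05, 1121 higher and 817 lower. GCD1 differed by 2.97 ± 0.48 and ABCE1 by -4.98 ± 0.83 (adjusted p = 0.198 for both), the Mediator subunit MED31 by 3.29 ± 0.66 (adjusted p = 0.511) and SCL26 by -0.22 ± 0.93. ABCE1 was also named in the nitrate effect in Col0 cortex and in 2 interactions. All of these use the same 2 Col0 cortex KNO3 arrays, so the ABCE1 results are not independent. Of the 4 gibberellin lists, 2 were lower as groups in arrays labelled atscl26. The biosynthesis list had 12 of 14 members lower (median -0.77, camera adjusted p = 0.037), with the oxidase genes GA20OX5 at -1.75 ± 0.70 and KAO2 at -2.72 ± 1.11. The signalling list had 10 of 12 lower (median -0.60, adjusted p = 0.0394), with the DELLA repressor RGA at -2.27 ± 0.67 and SPY, which modifies DELLA proteins, at -1.98 ± 0.99. Both had an adjusted p = 0.307 with an estimated correlation, and RGA alone passed when adjusted over the list alone (adjusted p = 0.0403), not over all models. Gibberellin catabolism (4 of 7 lower, median -0.159, adjusted p = 0.837) and GASA peptides (6 of 7 lower, median -0.493, adjusted p = 0.308) were not called. The GRAS family had 20 of 22 members lower (median -0.41, adjusted p = 0.043; adjusted p = 0.347 with an estimated correlation), with the radial patterning factor SCR at -1.64 ± 0.90 and SCL8 at -1.04 ± 0.57. Non-hair markers were higher (5 of 6, median 1.58, adjusted p = 0.00556; adjusted p = 0.307 with an estimated correlation), with MYB23 at 2.89 ± 0.83 and WER at 4.28 ± 1.62, both past the threshold when adjusted over the list alone (adjusted p = 0.0157 and 0.0495). Non-hair marker means were 10.47, 11.23 and 10.96 in the atscl26 arrays and 9.76 and 8.52 in the Col0 arrays. The replicate block (camera adjusted p = 0.0792 for both gibberellin lists, 0.088 for the GRAS family) and array weights (0.147 for both, 0.143) ended these 3 calls, and leaving out dim models ended that of biosynthesis (0.0837). For biosynthesis, signalling and GRAS the medians were -0.621, -0.456 and -0.257 with the block and -0.98, -0.616 and -0.541 with array weights, and -0.774 for biosynthesis with dim models left out. The gibberellin calls were also lost without the 4 low-correlation arrays (camera adjusted p = 0.272 and 0.146, medians -0.30 and -0.335, 37 models past the threshold) and without the discordant arrays (0.612 and 0.512, medians -0.384 and -0.293, 61 models), which leave 1 array in Col0 and in atscl26, respectively. The latter also ended the calls of the GRAS family (0.663, median -0.254) and of the non-hair markers (median 0.64, adjusted p = 0.512), which are part of the score that picks those arrays.

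The cell type effect in Col0 under KCl (n = 3 and 3) gave no model past the threshold in limma and 1616 with an unadjusted p under 0.05. PAL4 differed by 2.58 ± 0.43 (adjusted p = 0.221) and SCL26 by 1.28 ± 0.83. PAL4 passed with quantile normalization (adjusted p = 0.00536), array weights (0.000195) and without the 4 low-correlation arrays (0.0173). It did not pass with the replicate block or with an intensity trend and robust prior. The same Col0 epidermis KCl arrays enter the nitrate effect in Col0 epidermis and the genotype effect in KCl epidermis. The PAL4 results of these comparisons are therefore not independent. Epidermis markers were higher in arrays labelled epidermis, while cortex markers were not called. Cortex marker means were 10.68, 11.71 and 8.49 in the epidermis arrays and 10.29, 9.63 and 10.09 in the cortex arrays. Replicates 1 and 2 of the epidermis arrays were discordant, so the labels are in doubt here. Root hair markers (9 of 10, median 0.95, camera adjusted p = 0.00429) included COBL9 at 2.22 ± 0.62, which passed when adjusted over the list alone (adjusted p = 0.022) and not over all models, and RHD6 at 2.78 ± 1.17. Non-hair markers (median 1.60, adjusted p = 0.0317) included GL2 at 2.21 ± 0.79 and EGL3 at 2.09 ± 1.01. Endodermis markers were higher too (9 of 11, median 1.75, adjusted p = 0.0317), with CASP1 at 2.62 ± 1.34, and reductant supply was lower (8 of 8, median -0.78, adjusted p = 0.00319), with G6PD3 at -2.35 ± 0.86 and RFNR1 at -1.85 ± 1.04. All 4 calls had an adjusted p = 0.68 with an estimated correlation. Endodermis marker means were 8.58, 8.09 and 8.01 in the cortex arrays against 11.50, 9.16 and 7.10 in the epidermis arrays. Without the 4 low-correlation arrays the root hair and reductant calls were lost (camera adjusted p = 0.279 and 0.264, medians 0.0404 and -0.313). The endodermis call was lost with quantile normalization (0.0636, median 1.71). Array weights ended the endodermis and root hair calls (0.899 and 0.981, medians 0.022 and -0.0538).

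The average nitrate effect over both genotypes and cell types (n = 11 and 11) gave no model past the threshold in limma, 735 with an unadjusted p under 0.05 and no list called. The genes emb2738 (1.71 ± 0.31) and emb2726 (1.66 ± 0.30), both needed for embryo development, had an adjusted p = 0.591. NIA1 differed by -0.34 ± 0.28, NIA2, the second nitrate reductase, by -0.34 ± 0.24, NIR1 by -0.38 ± 0.41, NRT2.1 by -0.09 ± 0.50, the sensor and transporter NRT1.1 by -0.71 ± 0.47 and SCL26 by 0.29 ± 0.44 (adjusted p = 1 for each). The list of nitrate uptake and reduction had 7 of 9 members lower (median -0.34, camera adjusted p = 0.0604; adjusted p = 0.747 with an estimated correlation).

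The average genotype effect (n = 11 and 11) gave no model past the threshold in limma and 1527 with an unadjusted p under 0.05. QKY, a membrane protein of cell signalling, differed by -1.46 ± 0.31 (adjusted p = 0.806) and SCL26 by -0.11 ± 0.44 (adjusted p = 0.949). Stress genes were higher in arrays labelled atscl26 (13 of 14, median 0.34, camera adjusted p = 0.00399; adjusted p = 0.639 with an estimated correlation), with WRKY53 at 0.93 ± 0.32 and WRKY40 at 1.4 ± 0.56. Non-hair markers were higher (5 of 6, median 0.54, adjusted p = 0.016; adjusted p = 0.46 with an estimated correlation), with MYB23 at 1.08 ± 0.39 and CPC at 0.55 ± 0.26, and stele markers were lower (11 of 14, median -0.41, adjusted p = 0.024; adjusted p = 0.639 with an estimated correlation), with LHW at -0.60 ± 0.33. Gibberellin biosynthesis genes were lower in 13 of 14 cases (median -0.46, adjusted p = 0.079) and gibberellin signalling genes in 10 of 12 (median -0.39, adjusted p = 0.079). The kinase CDKB2;2 passed when adjusted over the list alone (-1.51 ± 0.46, adjusted p = 0.0453), not over all models. The stress and stele calls were lost without the 4 low-correlation arrays (camera adjusted p = 0.448 and 0.613, medians 0.131 and -0.0494). The non-hair and stele calls were lost with array weights (0.228 and 0.333, medians 0.479 and -0.198). All 3 calls were lost without the discordant arrays, which leaves some groups with 1 array (medians 0.248 for stress and 0.0745 for stele). Non-hair markers are part of the score that picks those arrays, so their change is no test. The discordant arrays labelled cortex were all labelled atscl26, with non-hair means of 11.17, 11.23 and 10.96, against 8.52 to 9.76 in Col0 cortex. Discordant arrays labelled epidermis came from both genotypes.

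The average cell type effect (n = 11 and 11) gave the only model past the threshold in the 15 comparisons. AT5G18150, which has no symbol in the reference, was higher in epidermis by 2.06 ± 0.26 (limma adjusted p = 0.00917). Its level lay between 9.15 and 10.87 in all 11 arrays labelled epidermis and between 7.0 and 8.71 in all 11 labelled cortex, and 1892 models had an unadjusted p under 0.05. Non-hair markers were higher in epidermis (6 of 6, median 0.43, camera adjusted p = 0.0108; adjusted p = 0.902 with an estimated correlation; median 0.237 and adjusted p = 0.0724 without the 4 low-correlation arrays), with WER at 1.87 ± 0.77 and GL2 at 1.53 ± 0.42, and SCL26 differed by 0.06 ± 0.44. Adjusted over the list alone, GL2 (adjusted p = 0.0105), the ammonium transporter AMT1;3 (2.00 ± 0.52, adjusted p = 0.0126), FIT, the iron deficiency regulator (1.63 ± 0.44, adjusted p = 0.0127), PHO2 (1.43 ± 0.37, adjusted p = 0.00741) and FEZ (1.1 ± 0.39, adjusted p = 0.0448) passed, and none did over all models. The call of AT5G18150 was lost with an intensity trend and robust prior, and in the fits without replicate 2 of atscl26 epidermis KCl or without replicate 1 of Col0 cortex KNO3, where 0 models passed in limma.

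Over the 15 comparisons, camera called 35 of 330 list tests, 20 of them of cell type markers, and none of the 35 held with an estimated correlation, where the smallest adjusted p was 0.247. In the same 330 tests, 21 member results passed when adjusted over the list alone, and none over all models. No adjustment was made across lists or comparisons, so some of these are due by chance and give no support alone. Of the 22 lists, 11 were called in at least 1 comparison. For the other 11 the smallest camera adjusted p was 0.0604 for nitrate uptake and reduction (average nitrate effect, median -0.34) and 0.0597 for nitrate response regulators (nitrate effect in atscl26 cortex, 16 of 22 lower, median -0.41). It was 0.338 for ammonium assimilation, 0.0867 for nitrogen starvation transporters (9 of 10 higher in Col0 KCl epidermis, median 0.70), 0.238 for gibberellin catabolism, 0.194 for GASA peptides and 0.131 for auxin and lateral root. It was 0.19 for cytokinin synthesis and response, 0.234 for iron deficiency, 0.0819 for phosphate starvation (average genotype effect, 5 of 6 lower, median -0.51) and 0.131 for root cap markers.

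**Figure D4:**
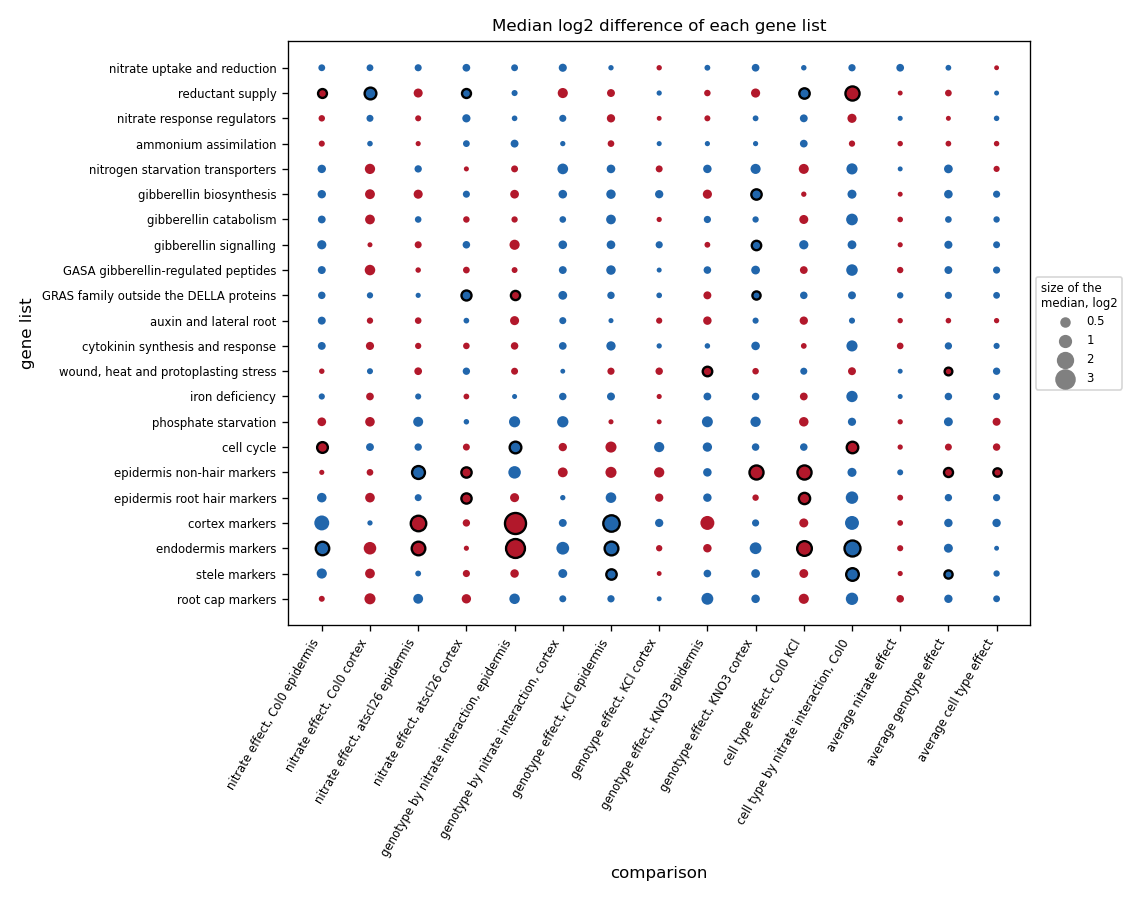
Median log2 difference of each of the 22 gene lists in each of the 15 comparisons, with red for higher, blue for lower, area for size and a black ring for the 35 lists past the camera threshold with the preset correlation. Medians of cortex and endodermis markers in the epidermis interaction, 3.79 and 3.02, were among the called values.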

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

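The tests of marker levels and of low array correlation were chosen after the results had been seen, while the counts over other splits of the arrays were planned. A total of 8 gene list results differed between groups by a test of the difference itself, the interaction term in camera, and all 8 lost their call with an estimated correlation (adjusted p = 0.522 to 0.691). In epidermis, the nitrate effect was more positive in arrays labelled atscl26 than in those labelled Col0 for cortex markers (median 3.79), endodermis markers (median 3.02) and the GRAS family outside the DELLA proteins (median 0.56), and more negative for cell cycle genes (median -1.03). In Col0, the nitrate effect was more positive in epidermis than in cortex for reductant supply (median 1.60) and cell cycle genes (median 1.00), and more negative for endodermis markers (median -2.10) and stele markers (median -1.24). No group held enough arrays for the search for single arrays far from their group, which needs at least 4.

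The first pattern weighed is that 6 well correlated arrays had marker scores nearer the other cell type, chosen because markers of cortex and endodermis had the largest medians among these interactions. An effect of genotype or treatment on the marker genes is argued against where replicates of 1 group differ. In atscl26 epidermis KNO3 the marker score spanned 4.52 on the log2 scale, against 1.72 between the medians of the cell types. It spanned 3.59 in atscl26 cortex KCl. The span of 2.45 in Col0 epidermis KCl includes the low-correlation replicate 2 (-1.90). Its well correlated replicates 1 and 3 had scores of -1.49 and 0.55. These lie no further apart than the medians of the concordant well correlated arrays, 0.94 in epidermis and -1.49 in cortex. An effect on the markers is thus not clearly argued against in that group. In atscl26 cortex KNO3 both well correlated arrays were discordant and WER was 12.69, 13.24 and 13.07, so such an effect is not argued against there. Exchanged labels stay open: all 6 arrays correlated better with arrays of the other cell type, 3 from each label, but 1 model, AT5G18150, separated all 22 arrays by the given labels, and 5 of 100 splits of the arrays gave as many such models (highest 2 in another split). Replicates 2 and 3 of atscl26 KNO3 were discordant under both labels, with scores of -1.29 and -3.53 in epidermis and -0.145 and 1.56 in cortex. Replicate 1 of Col0 epidermis KCl had no such counterpart (-1.58 in cortex). That of replicate 3 of atscl26 cortex KCl was removed by the submitters. A minority of cells of the other type in the sort would lower the markers of the labelled type by under 1 on the log2 scale. The mean fall of GL2, WER, EGL3 and RHD6 was 3.47 and 1.83 in replicates 3 and 2 of atscl26 epidermis KNO3. That of AT1G62510 and C/VIF2 was 2.04 in replicate 3 of atscl26 cortex KCl. Each was over 1 by more than the SD over markers, which in cortex rests on 2 genes. The falls lay within 1 SD of 1 in Col0 epidermis KCl replicate 1 (1.17) and atscl26 cortex KNO3 replicates 2 and 3 (-0.11 and 2.01). The median over the 6 arrays was 1.92. These markers are part of the score that picked the arrays, so a fall was built in and its size decides nothing. Exchanged labels and mixed sorts, by a minority or more, both stay open.

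The second pattern is that 4 arrays correlated poorly with all others. The 4 arrays were picked by Pearson correlation, which a linear difference of scale leaves unchanged, so such a difference could not have made the pattern. A nonlinear one that keeps the order of the models is argued against by ranks. The highest median rank correlation of the 4 arrays was 0.802, against a lowest of 0.856 in the other 18. A compressed signal range with a raised floor was seen: the lowest lower quartile of the 4 arrays was 7.31, above the highest of the others, 7.25, and their SD was 1.99 to 2.24 against 2.31 to 2.51. This is consistent with weak or degraded input, which was not tested, and no biological explanation was tested.

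For the planned comparisons with at least 3 arrays per group, other splits of the same arrays were counted, and with 10 splits of 3 against 3 no share under 0.05 can be reached. In these, the number of models with an unadjusted p under 0.05, the splits with as many and the highest of the other splits were 1711, 10 and 6654 for the nitrate effect in Col0 epidermis, and 859, 3 and 2120 for that in atscl26 cortex. For the genotype effect they were 1633, 3 and 1949 in KNO3 epidermis and 409, 4 and 487 in KCl cortex, and for the cell type effect in Col0 KCl 1616, 6 and 2365. Called lists numbered 3 in the nitrate effect in Col0 epidermis (5 splits with as many, highest other 6), 4 in that of atscl26 cortex (1 split, the real one, highest other 3), 1 in the genotype effect in KNO3 epidermis (8 splits, highest other 6) and 4 in the cell type effect in Col0 KCl (6 splits, highest other 6).

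For the average effects, 100 splits were drawn, and chance could not be excluded for any count. The number of models with an unadjusted p under 0.05 was 735 for nitrate, reached by 69 splits (highest other 8082), 1527 for genotype, reached by 39 (highest other 6770), and 1892 for cell type, reached by 16 (highest other 8594). The 1 model past the threshold for cell type was matched by 5 splits (highest other 8). The 3 lists called for genotype were matched by 44 splits and the 1 list for cell type by 84 (highest other 9 in both). Some splits gave several times the real counts, and 278 models passed the threshold in a split for genotype, for reasons not tested here.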

How the results depend on the processing

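The settings without the 4 low-correlation arrays and without the discordant arrays, and the list tests with 1 array left out, were chosen after the data had been seen, and the others were planned. The limits are the unequal arrays and the group sizes of 2 or 3, and weak signals lie near the floor of the arrays, where log2 differences are compressed. Outside the settings that leave out 1 array, named genes kept their direction and their side of the threshold in 988 of 1053 cases, passed it in 34 (25 with array weights), lost it in 1 and turned in 30. Only 1 named gene, AT5G18150, passed in the main fit. Nearly all of the 988 cases were therefore below the threshold in both fits, so their share is no measure of stability. The 35 list calls kept call and direction in 31 cases with quantile normalization, 31 with the replicate block, 23 with dim models left out, 18 without the 4 low-correlation arrays and 15 with array weights. Without the discordant arrays 2 of 26 did so, but this leaves some groups with 1 array, and the epidermis and cortex marker lists hold the genes that pick the arrays, so it tests neither. Quantile normalization moved the median of all models by at most 0.0596. With 1 model per locus no count changed. No scanner files were used, so background correction was not varied. Quantile normalization ended the calls of reductant supply for nitrate in Col0 epidermis, of cortex markers for nitrate in atscl26 epidermis and for genotype in KCl epidermis, and of endodermis markers between cell types in Col0 KCl. The replicate block ended those of cortex markers for genotype in KCl epidermis and of both gibberellin lists and the GRAS family for genotype in KNO3 cortex. The cause of the changes below was not tested here, except that an estimated correlation allows, by construction, for members of a list that vary together.

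Counts of models past the threshold, 0 unless stated, moved as follows. With quantile normalization they were 1 for the nitrate effect in Col0 epidermis, 1 for the genotype effect in KCl epidermis and 2 for the cell type effect in Col0 KCl. For the genotype effect in KNO3 epidermis it was 1 with dim models left out and 1 with only the groups compared in the fit. Array weights gave 3486 for the cell type effect in Col0 KCl, 963 and 519 for the nitrate effect in atscl26 cortex and Col0 epidermis, 249, 167 and 91 for the genotype effect in KCl cortex, KCl epidermis and KNO3 epidermis, and 90 for the interaction in epidermis. These weights ran from 0.081 to 8.71, so some groups rest mostly on 1 array. The intensity trend with a robust prior took the average cell type effect from 1 to 0, and the estimated correlation took the gene list tests from 35 to 0. Without the 4 low-correlation arrays the counts were 11 and 24 for nitrate in Col0 epidermis and cortex, 2 and 10 for the interaction in epidermis and cortex, 1, 14 and 37 for genotype in KCl epidermis, KNO3 epidermis and KNO3 cortex, 1 for cell type in Col0 KCl, 8 for its interaction with nitrate, and 1, 3 and 25 for the average nitrate, genotype and cell type effects. Without the discordant arrays they were 89 for nitrate in atscl26 cortex, 3 for the interaction in cortex and 61 for genotype in KNO3 cortex.

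The replicate numbers do not pair the arrays. Deviations from the group means of same-numbered arrays correlated between -0.58 and 0.35 over 71 pairs (19 over 0.1), and 4 of 22 arrays correlated best with their own number. Those of differently numbered arrays correlated between -0.43 and 0.58 over 140 pairs (40 over 0.1). With the replicate block the count stayed at 1 for the average cell type effect and 0 elsewhere in limma, 33 lists were called, and SCL26 turned to 0.067 in the genotype effect in KNO3 cortex.

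Directions turned for the following log2 values, none of them past the threshold by itself. With array weights, NRT2.1 was 0.072 for nitrate in Col0 epidermis and 0.062 on average, SCL26 was 0.034 for genotype in KCl epidermis and 0.27 on average, and list medians were 0.23 for endodermis markers under nitrate in Col0 epidermis, 0.084 for stele markers in the genotype effect in KCl epidermis and -0.0538 for root hair markers in the cell type effect in Col0 KCl. The endodermis median in the latter stayed positive, at 0.022. Without the 4 low-correlation arrays, NRT2.1 was 0.079, -0.26 and -0.15 for nitrate in Col0 epidermis, Col0 cortex and atscl26 cortex, NIA1 was 0.16 and NIR1 0.14 in Col0 cortex, NIR1 was 0.20 on average, and SCL26 was 1.22 for genotype in KNO3 cortex and 0.46 on average. Without the discordant arrays, values for nitrate in Col0 epidermis were -0.48 for CDKB2;2, 0.64 for CASP2, 0.17 for CASP5, 0.44 for NRT2.1 (0.53 on average), -0.48 for the cell cycle list and 0.86 for endodermis markers. In atscl26 epidermis they were -0.0042 for AT1G62510, -0.043 for MYB36, -0.57 for SGN3, -0.12 for the endodermis list and -0.0042 for the cortex list. In the epidermis interaction they were 0.27 for MCM2, -0.095 for C/VIF2, -0.55 for SGN3, -0.088 for CASP5, and -0.16, 0.58, -0.095 and -0.98 for the lists GRAS, cell cycle, cortex and endodermis. For genotype in KCl epidermis they were 0.19 for SCL26, 0.17 for C/VIF2, 0.55 for PER64, 0.21 for the endodermis list, 0.17 for the cortex list and 0.12 for the stele list. On average the stele list was 0.0745 for genotype, and SCL26 was 0.37 for genotype in KNO3 cortex and 0.53 on average.

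Leaving out 1 array at a time gave these ranges of counts. For nitrate they were 0 to 5 in Col0 epidermis (5 without KCl replicate 1, 2 without KNO3 replicate 2), 0 to 884 in Col0 cortex (884 without KNO3 replicate 2, which leaves 1 array of low correlation), 0 to 21 in atscl26 epidermis (21 and 2 without KCl replicates 2 and 1), and 0 to 1 in atscl26 cortex (1 without KCl replicate 3). The interactions gave 0 to 4 in epidermis (4 without atscl26 KCl replicate 2, 2 without Col0 KNO3 replicate 2) and 0 to 138 in cortex (138 without Col0 KNO3 replicate 2). Genotype gave 0 to 25 in KCl epidermis (25 without atscl26 replicate 2), 0 to 1 in KCl cortex (1 without Col0 replicate 3), 0 to 1 in KNO3 epidermis (1 without Col0 replicate 2 or atscl26 replicate 1) and 0 to 660 in KNO3 cortex (660 without Col0 replicate 2, 1 without Col0 replicate 1 or atscl26 replicate 3). Cell type in Col0 KCl gave 0 to 30 (30 without epidermis replicate 1, 1 without cortex replicate 3), and its interaction with nitrate 0 to 674 (674 without cortex KNO3 replicate 2, 5 without epidermis KCl replicate 1). The averages gave 0 to 3 for nitrate (3 without Col0 cortex KNO3 replicate 2, 1 without atscl26 cortex KNO3 replicate 2), 0 to 30 for genotype (30 without Col0 cortex KNO3 replicate 2, 1 without Col0 epidermis KNO3 replicate 3) and 0 to 3 for cell type (3 without Col0 cortex KNO3 replicate 2, 2 without atscl26 cortex KCl replicate 3, 0 without replicate 1 of Col0 cortex KNO3 or replicate 2 of atscl26 epidermis KCl). List calls ranged from 21 to 50, with 21 without Col0 epidermis KCl replicate 1. Among named genes whose direction turned, the ranges for nitrate were -1.27 to 0.029 (NIA1) and -1.61 to 0.61 (NRT2.1) in Col0 epidermis, -0.79 to 0.16 (NIA1), -4.31 to 0.14 (NIR1) and -0.26 to 2.2 (NRT2.1) in Col0 cortex, -0.70 to 0.20 (NIA1) and -0.33 to 0.99 (NIR1) in atscl26 epidermis, and -0.39 to 0.053 (NIA1) and -0.15 to 1.15 (NRT2.1) in atscl26 cortex. On average they were -0.94 to 0.17 (NIR1) and -0.40 to 0.27 (NRT2.1), and SCL26 ranged from -1.96 to 1.52 for genotype in KNO3 cortex and from -0.54 to 0.33 on average.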

Other observations

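All values in this part were chosen after they had been seen. EN7, an endodermal gene, was 11.83 to 12.36 in the 3 well correlated discordant arrays labelled epidermis, against 6.63 to 9.75 in the 6 concordant epidermis arrays and 11.02 to 13.07 in the 6 concordant cortex arrays. CASP1, of the Casparian strip, ranged from 8.15 to 13.38 in the same 3 arrays, from 7.70 to 10.16 in the concordant epidermis arrays and from 7.86 to 11.57 in the concordant cortex arrays. ESB1 ranged from 9.04 to 13.01, 7.31 to 11.94 and 7.99 to 9.14 in the same order. These 3 genes stand for themselves and not for all 11 endodermis markers.

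AT5G18150 kept the side of its label in the discordant arrays too. It was 9.67 to 9.99 in the well correlated ones labelled epidermis, 9.21 in replicate 2 of Col0 epidermis KCl and 7.04 to 8.06 in those labelled cortex. It was the only one of 31524 models that separated the cell type labels of all 22 arrays.

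The authors' table of group averages equals the mean of the group's own arrays in 6 of its 8 columns. The column for Col0 cortex KNO3 equals the mean of its 2 arrays and replicate 1 of atscl26 cortex KCl, which moves 230 models by over 1 on the log2 scale (at most 1.74). The column for the Col0 epidermis control equals the mean of replicates 1 and 3 and of replicate 1 of atscl26 epidermis KNO3, without the low-correlation replicate 2, which moves 5547 models by over 1 (at most 2.61). Both borrowed arrays also enter the column of their own group. Which table carries the right labels cannot be settled from the sources used here, so the comparisons that use these arrays may rest on a wrong label.

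The highest correlation between 2 arrays was 0.965, between replicate 3 of atscl26 cortex KCl and replicate 3 of atscl26 cortex KNO3, which are both discordant, and 0% of their values were identical. Within groups, correlations ran from 0.541 to 0.869 in Col0 epidermis KCl and from 0.928 to 0.943 in Col0 cortex KCl.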
